A study of Drosophila melanogaster with 7 samples.

How the data were processed

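Total RNA was extracted with Trizol from brains dissected in cold buffer and treated with DNase I, and bulk libraries were made by an adapted CEL-seq2 protocol, per the labels' protocols. CEL-seq2 primes on the poly(A) tail and reads the 3' end of each transcript, so circular RNA without a tail is not captured. STAR and the genome build dm6 are named in the submitters' processing notes; the counting tool, annotation, strand setting and use of molecular identifiers are not given in the sources used here. The deposited table holds normalized counts, a signal whose making by the authors is not given beyond that name in the sources used here. In the intact lines every value above 0 was a whole multiple of one step per library (100% of values within 0.001 of a read), as whole counts divided by 1 factor per library are. The totals recovered in this way give the depth, from 3260649 to 5546121; they are called reads here, and could be molecules. Counting error alone limits genes near the minimum used here, a mean of 10 normalized counts. A rescaling by median-of-ratios factors over the 7 libraries gave the same factor, 1.008, for each of them.

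In the deposited table, 14476 intact gene lines were used. A run of 2139 lines holds a misplaced stretch of another table, with text and counts under unnamed headings, and 1 further line has a damaged name. These lines and 402 columns without a sample were not used, so the genes on those lines, many on 2L (800) and 3R (768), are not analysed here. Symbols were matched to gene IDs by current symbol (11208) or by a synonym in the RefSeq gene table of assembly Release 6 plus ISO1 MT (3150), and 118 were not matched. Positions come from the Ensembl BDGP6 annotation, the same assembly as dm6. Columns were assigned to samples by title, groups and replicate numbers come from the source names, and date, lane and title numbers were read from the titles.

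Values were log2-transformed after adding a pseudocount of 1. Genes with a mean of at least 10 over the 7 libraries (7287) were compared between 2 knockdown and 5 control libraries with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), without covariates. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Of 29 gene lists fixed before the data were examined, 28 had at least 5 measured members and were tested with camera (preset correlation 0.01, and again with an estimated correlation). Named genes were chosen by a rule also fixed then: mbl; the 10 largest rises and 10 largest falls among genes past the test with a mean of at least 50 and no overlap of groups, leaving out symbols that are a bare CG or CR number; up to 4 members of each list with the smallest p; and sex and background markers. For mbl, a comparison of its values alone used a two-sided exact permutation test over the 21 ways to pick 2 of 7 libraries (scipy 1.17.1). No pair of libraries was counted as 1 sample: the median chi-square per gene between libraries of a lane code was between 0.98 and 1.23 (0.455 from sampling noise alone) and the mean between 5.73 and 8.92. Between lane codes, knockdown libraries included, the median was between 2.91 and 4.67, and it was 3.52 and 3.23 for the same-titled control pairs. The other pairs of L5 and L7 controls gave 4.67 and 4.21 for control replicate 2, and 3.77 and 3.49 for control replicate 3. Control replicate 4 was thus as close to control replicate 3 (3.49) as to the same-titled control replicate 2 (3.52). That comparison cannot tell whether these pairs share their RNA, since lane code alone separates libraries. The log2 difference between controls of title numbers 3 and 2 correlated between lane codes across 5082 genes (r = 0.42). That of 3 and 2 in L5 correlated with that of 3 and 1 in L7 (r = 0.37). Both differences in the latter hold a title 3 library, so r = 0.37 does not count against shared RNA. Hsp22, picked after its values were seen, held 219.5 and 203.6 normalized counts in the title 3 pair. In the title 2 pair it held 31 and 29.6. Hsp27, at low counts, differed within the title 3 pair (6.4 and 22.4). The rhodopsin gene ninaE, also picked after its values were seen, held 1840 and 2072 in the title 3 pair. In the title 2 pair ninaE held 445.2 and 459.3. The knockdown libraries, of another genotype, followed title number too, with 1920 for number 3 and 599.2 for number 2. A value that follows title number thus cannot by itself decide whether a pair shares RNA. Shared RNA was left open and the controls were kept as 5 libraries, which overstates the number of control samples if these pairs share it. The gene and list tests were checked on simulated data of the comparison of 2 with 5 libraries: among 7287 genes with 200 changed, 28.4% of those changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. There were 9 false calls among 152, and 0 of 40 unchanged lists were called. Genes were simulated independently of each other, with 1 dispersion (0.0182) and no difference between lane codes. These rates therefore do not cover controls that differ by lane code or lists of correlated genes. Alternatives covered the pseudocount, the filter, rescaling, quantile normalization, the variance model, library weights, averaged or correlated same-titled controls, replicate blocks, lane codes, leaving out each library, voom on the recovered reads and the thresholds. After the data were seen 3 were added: a test against the controls of each lane code, reads thinned to the smallest library, and an estimated correlation without the filter for the list that only then had at least 5 members. Figures were drawn with matplotlib 3.10.9.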

Results

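Gene expression was measured by 3' RNA-seq in dissected brains of Drosophila melanogaster, with 5 libraries from control flies and 2 from flies in which circMbl, a circular RNA made from the muscleblind (mbl) gene, was knocked down. Both genotypes carried the ubiquitous Actin-GAL4 driver, with a short hairpin against circMbl in the knockdown and a hairpin with 8 mismatches in the control, and all library titles name day 3. The comparison asks which brain transcripts differ when the circular RNA is depleted. Control replicates 1 to 5 held 5546121, 3918134, 4224478, 3732675 and 5177575 counted reads in the gene lines used, and knockdown replicates 1 and 2 held 3260649 and 3308580. No label states whether libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. The titles give every control library one date code and both knockdown libraries another, with lane codes L7 (control replicates 1, 4 and 5), L5 (control replicates 2 and 3) and L2 (both knockdown libraries). Control replicates 2 and 4 share the title number 3, and control replicates 3 and 5 the title number 2, each pair across lane codes L5 and L7. The labels do not say whether such a pair comes from the same RNA, in which case the 5 control libraries stand for 3 samples. With these pairs averaged 1301 genes passed and mbl passed (limma, adjusted p = 0.0368). Each average joins an L5 and an L7 library, which evens out the lane difference within that pair. The higher count is thus no sign of a firmer result.

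Transcripts of mbl, the host gene of the targeted circle (FBgn0265487, 2R from 17216549 to 17379376 on BDGP6, the dm6 assembly), stood at 3323, 3602, 4122, 3341 and 3430 normalized counts in control replicates 1 to 5 and at 2770 and 2304 in knockdown replicates 1 and 2. The means were 3564 ± 331 (SD, n = 5) and 2537 ± 329 (SD, n = 2), a log2 fold change of -0.49 ± 0.14 (SE) that did not pass the limma test over all genes (adjusted p = 0.0694). A two-sided exact permutation test of the same values gave p = 0.0952. That is the smallest p that this form of the test, which doubles the smaller tail, allows with 5 against 2 libraries. Against the controls of each lane code separately, a test chosen after the data were seen, the difference passed (limma, adjusted p = 0.04, with a range of 0.00946 to 0.37 over the alternatives tried). These reads come from polyadenylated 3' ends, so they do not measure the circular RNA and do not check the knockdown itself.

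Knockdown brains differed from control brains in 445 of 7287 genes tested, 253 higher and 192 lower (limma, adjusted p under 0.05). In a fit with the L7 controls alone the falls outnumbered the rises (1339 and 1070). Among changed genes with a mean of at least 50 normalized counts and no overlap of groups, the 10 largest rises and 10 largest falls were named. Symbols that are a bare CG or CR number were left out, and some of these changed more. The largest of these rises was that of ATP6, a mitochondrially encoded subunit of ATP synthase, from 48.9 ± 7.13 normalized counts (SD, n = 5) to 653.3 ± 0.649 (SD, n = 2), a 13.2-fold difference on the log2(value + 1) scale. The feeding-responsive fat body transcript fit rose 6.7-fold, the pigmentation gene y (yellow) rose 3.51-fold and U2af38, the small subunit of the splicing factor U2AF, rose 3.1-fold. The largest of these falls was that of the alkaline phosphatase gene phu, from 94.6 ± 36.4 (SD, n = 5) to 19.6 ± 5.35 (SD, n = 2), 4.46-fold lower. The NF-kappa-B factor dl (dorsal) was 2.96-fold lower, and Arc1, which encodes a capsid-forming synaptic protein, was 2.42-fold lower.

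By the naming rule, these genes came from the 382 changed genes with that mean and no overlap between knockdown and control libraries. If the 7 libraries were exchangeable, 9.5% of genes would show that separation by chance. Libraries group by lane code, so that share does not hold here. The separation adds no support for genes already chosen by the limma test. ATP6 had a log2 fold change of 3.73 ± 0.18 (SE) with an adjusted p of 3.38e-05 in the limma test. The gene fit (FBgn0038914, 3R from 21883924 to 21884454) had 2.75 ± 0.45 and an adjusted p of 0.015. The gene y (FBgn0004034, X from 356509 to 361245) had 1.81 ± 0.16 and an adjusted p of 0.00406, and U2af38 (FBgn0017457, 2L from 292959 to 294681) had 1.63 ± 0.16 and an adjusted p of 0.00457. The other raised genes were Tapdelta, a subunit of the translocon-associated complex of the endoplasmic reticulum (2.87-fold), the yolk protein gene Yp3 (2.82-fold), mitochondrial cytochrome b (CYTB, 2.79-fold), the nuclear receptor gene Hr4 (2.79-fold), the ribosomal stalk protein gene RpLP2 (2.76-fold) and the cytochrome P450 gene Cyp6a20 (2.75-fold). Their adjusted p-values lay between 0.00481 (CYTB) and 0.0282 (RpLP2) in the same limma test. Among the falls, phu (FBgn0043791, 3R from 9494801 to 9496723) had -2.16 ± 0.35 with an adjusted p of 0.014. The log2 fold change of dl (FBgn0260632, 2L from 17436830 to 17450364) was -1.57 ± 0.31 with 0.0249, and that of Arc1 (FBgn0033926, 2R from 14357927 to 14360297) was -1.275 ± 0.15 with 0.00613. The other lowered genes were Myo31DF, a class I myosin (2.75-fold), CHKov2 (2.5-fold), the follistatin gene Fs (2.38-fold), the bestrophin chloride channel gene Best1 (2.31-fold), the mitochondrial ribosomal protein gene mRpL52 (2.17-fold), ATP citrate lyase (ATPCL, 2.16-fold) and l(2)37Bb (2.14-fold). Their adjusted p-values lay between 0.0097 (l(2)37Bb) and 0.0424 (CHKov2). Some named rises and falls also differed between L5 and L7 controls in a limma fit of 3 groups (knockdown, L5, L7). They were RpLP2 (adjusted p = 9.3e-05), CHKov2 (0.000577), ATPCL (0.00299), Tapdelta (0.0048), Fs (0.00665), dl (0.0324) and Arc1 (0.0451). The log2 difference of RpLP2 was 0.927 against L5 and 1.822 against L7 controls. For CHKov2 it was -0.775 and -1.688. A bare CG or CR number, not named by this rule, stood above the last named gene 5 times among the rises and 7 times among the falls.

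**Figure D1:**
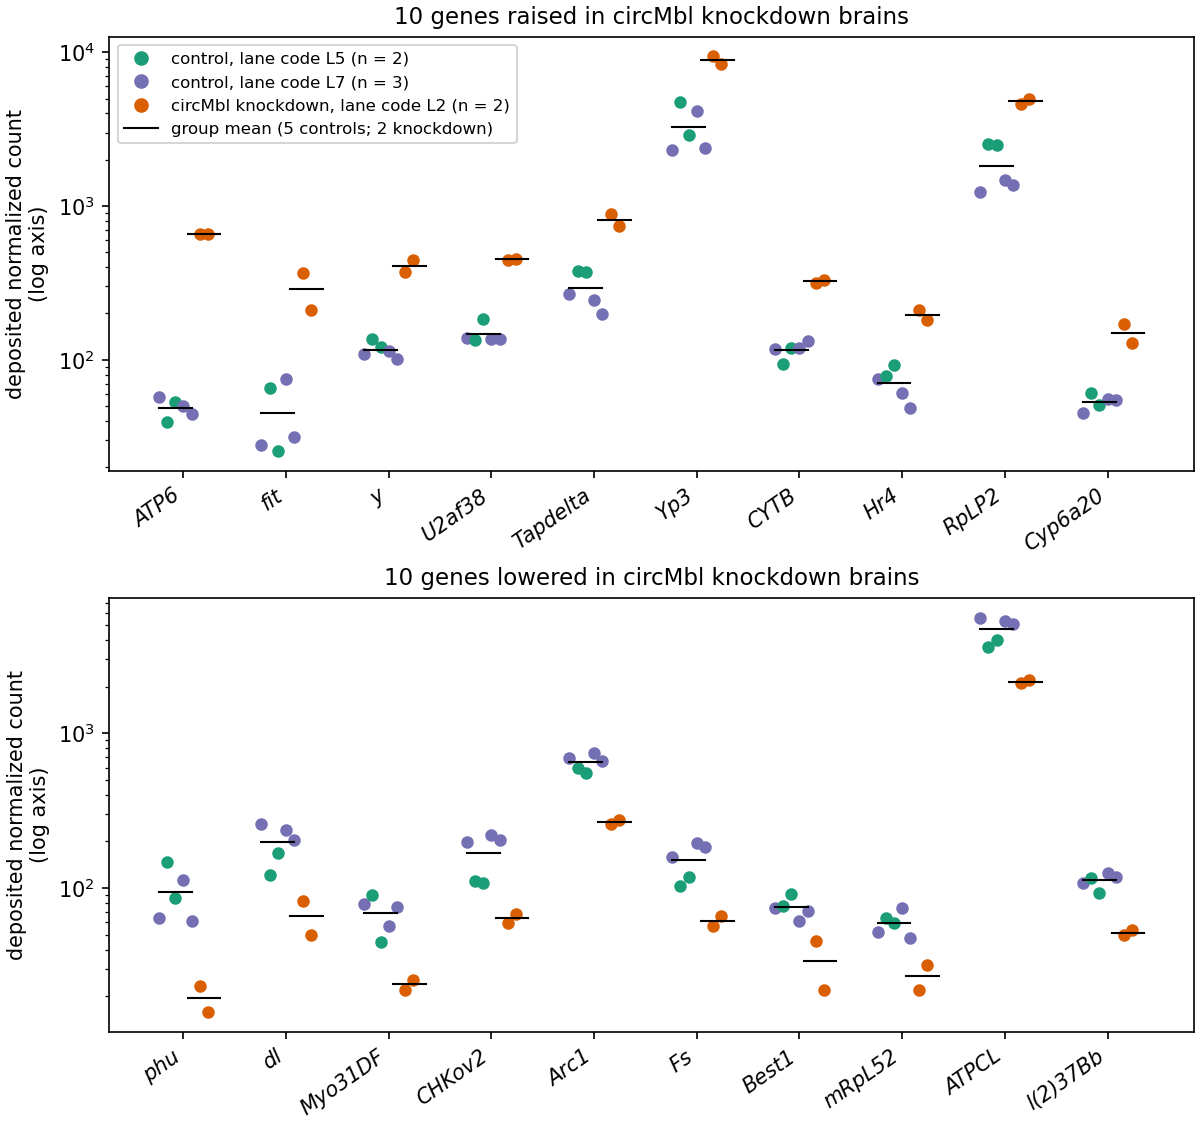
Deposited normalized counts (log axis) of the 10 raised and 10 lowered genes in each of the 5 control libraries, coloured by lane code, and the 2 knockdown libraries; bars mark group means. In all 20 genes both knockdown libraries lie outside the range of the 5 controls, which the naming rule required. Changes run from the 13.2-fold rise of ATP6 to the 4.46-fold fall of phu.

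The number of genes rests on both knockdown libraries: without either one, which sets a single library against 5 and assumes that it varies as the controls do, 1 gene (ATP6) passed; without control replicate 1, 4 or 5 the count was 202, 177 or 133. Date and lane code cannot be told apart from genotype, and in a limma fit of all 7 libraries as 3 groups controls of lane code L5 differed from controls of lane code L7 in 2057 genes, against 1571 genes between knockdown and L5 controls and 2445 between knockdown and L7 controls, with 375 of the 445 genes passing against both lane codes in the same direction (a test chosen after the data were seen).

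**Figure D2:**
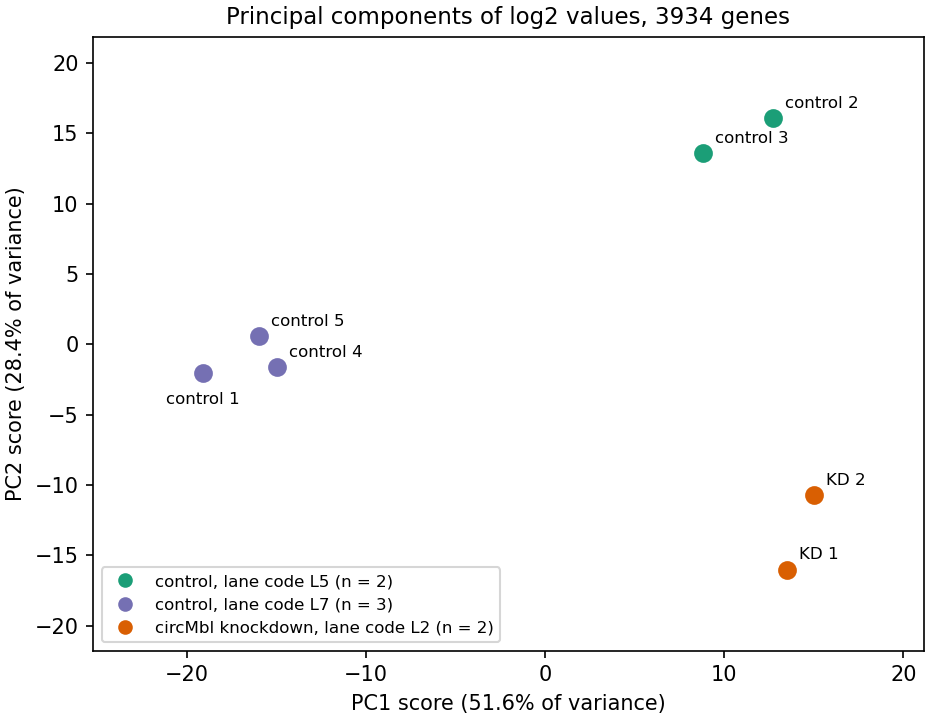
Scores of the 7 libraries on the first pair of principal components of log2 values over 3934 genes, with colours for lane code and genotype. PC1 (51.6% of variance) parts the L7 controls from the L5 controls and the knockdown libraries, and PC2 (28.4%) parts the knockdown libraries from the L5 controls.

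Fat body and yolk transcripts, heat shock genes, proteasome genes, sex-composition markers and genetic background markers were higher in knockdown brains as lists, and muscle genes were lower. These 6 of the 28 lists tested passed camera with the preset correlation of 0.01. With an estimated correlation between genes 0 of the 28 passed camera, with adjusted p-values from 0.651 to 0.979 and 1 list, that of sex-composition markers, at an unadjusted p under 0.05. Lists of glial, synaptic and neuropeptide genes did not pass. The median log2 fold change and the direction of camera differed in sign for the synaptic (-0.10), unfolded protein response (-0.11) and neurotransmitter (-0.01) lists, and median (0.07) and mean (-0.01) did for glycolysis.

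In the list of fat body and hemolymph genes, which marks tissue that can stay on a dissected brain, 3 of 13 measured members rose and 10 did not pass (7 rose adjusted over the list alone). The risers were fit, tobi, a glucosidase gene (5.9-fold), and Yp3, from 3285 ± 1090 (SD, n = 5) to 8901 ± 685 (SD, n = 2). The larval serum protein gene Lsp2 had a log2 fold change of 2.43 that did not pass (limma, adjusted p = 0.0714). The list was higher by camera (adjusted p = 0.00249; adjusted p = 0.724 with an estimated correlation), with a median log2 difference of 0.56 against L5 controls and 1.04 against L7 controls. Of the 11 sex-composition markers 2 rose, fit and Yp3 (4 rose adjusted over the list alone). As a list they were higher (camera, adjusted p = 0.0117; adjusted p = 0.651 with an estimated correlation). Against the L7 controls alone it did not pass (adjusted p = 0.0595; 0.00123 to 0.651 over the alternatives). It shares 4 measured members with the fat body list, so these calls are not independent. The sex-composition list joins the male-specific RNAs roX1 and roX2 with yolk protein genes. Its direction therefore does not measure the share of males or females. The other yolk protein genes did not pass, with log2 fold changes of 1.18 for Yp1 and 0.92 for Yp2 (limma, adjusted p = 0.102 and 0.0889). Control replicates 1 to 5 held 5277, 15708, 9045, 9267 and 5056 normalized counts of Yp1, and the knockdown libraries held 19232 and 17441. For Yp2 these values were 7957, 15163, 8657, 13319 and 7442 against 20562 and 17637, and for Yp3 2302, 4740, 2877, 4131 and 2376 against 9385 and 8416. The male-specific dosage compensation RNA roX1 stood at 60994, 31094, 43278, 47361 and 46974 in the controls and at 31599 and 26217 in the knockdown libraries (log2 fold change -0.64, limma adjusted p = 0.139). Its partner roX2 stood at 1080, 625, 686, 856 and 891 against 794 and 924 (0.08, adjusted p = 0.849). The sign of the roX2 difference turned against the L7 controls alone (-0.13) and without control replicate 2 or knockdown replicate 2.

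Of 17 measured heat shock genes 2 rose and 15 did not pass (6 rose adjusted over the list alone). Hsp83, the fly Hsp90, rose from 1353 ± 138 (SD, n = 5) to 2545 ± 694 (SD, n = 2), and the Hsp40 co-chaperone gene DnaJ-1 rose 1.91-fold. The inducible gene Hsp70Aa stood at 2.3, 12.8, 1.8, 19 and 2.5 normalized counts in the controls and at 345.7 and 29.2 in knockdown replicates 1 and 2, and did not pass (limma, adjusted p = 0.0529). Hsp70 genes are near-identical copies, whose reads the authors' counting could have split. The list was higher (camera, adjusted p = 0.00331; adjusted p = 0.724 with an estimated correlation), and without knockdown replicate 1 it did not pass (adjusted p = 0.195; 7.34e-08 to 0.724 over the alternatives). Of 29 measured proteasome genes 2 rose, Rpn1 (2.3-fold) and Rpt3 (2.35-fold), both in the regulatory particle, and 27 did not pass (7 rose adjusted over the list alone). The proteasome list was higher (camera, adjusted p = 0.00507; adjusted p = 0.724 with an estimated correlation), with a median log2 difference of 0.01 against L5 controls and 0.46 against L7 controls. Against the L5 controls alone it did not pass (adjusted p = 0.344; 0.000273 to 0.724 over the alternatives).

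Of 23 measured muscle genes 3 fell and 20 did not pass (3 fell adjusted over the list alone). They were SERCA, the calcium pump of the sarcoplasmic reticulum (1.55-fold lower), the troponin C gene TpnC41C (2.55-fold lower) and the muscle LIM protein gene Mlp60A (1.99-fold lower). TpnC41C held only 9.1 and 8.5 normalized counts in the knockdown libraries. The list was lower (camera, adjusted p = 0.0117; adjusted p = 0.724 with an estimated correlation), and did not pass without knockdown replicate 1 (adjusted p = 0.203) or against the L5 controls alone (0.114). It also did not pass with a mean of at least 50 normalized counts (0.146; 0.000517 to 0.724 over the alternatives). Of 6 measured genetic background markers 2 rose, y and the eye pigment transporter gene w (2 adjusted over the list alone). This list was higher (camera, adjusted p = 0.0379; adjusted p = 0.724 with an estimated correlation). That call ended without control replicate 3 (adjusted p = 0.0686), control replicate 5 (0.0514) or knockdown replicate 2 (0.0601), and against the L5 (0.148) or L7 (0.0595) controls alone. It also ended with quantile normalization (0.0637) and with same-titled controls averaged (0.0587), within 0.0206 to 0.724 over the alternatives. Normalized counts of y were 108.9, 136.3, 121.1, 114.1 and 100.4 in the controls and 373 and 447 in the knockdown libraries, and those of w were 94.1, 80.5, 87.4, 78.3 and 88.1 against 157.3 and 181.5. The eye colour gene v held 59.1, 81.4, 45.5, 81.7 and 53.5 against 96.2 and 76.7 and did not pass (limma, adjusted p = 0.314).

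**Figure D3:**
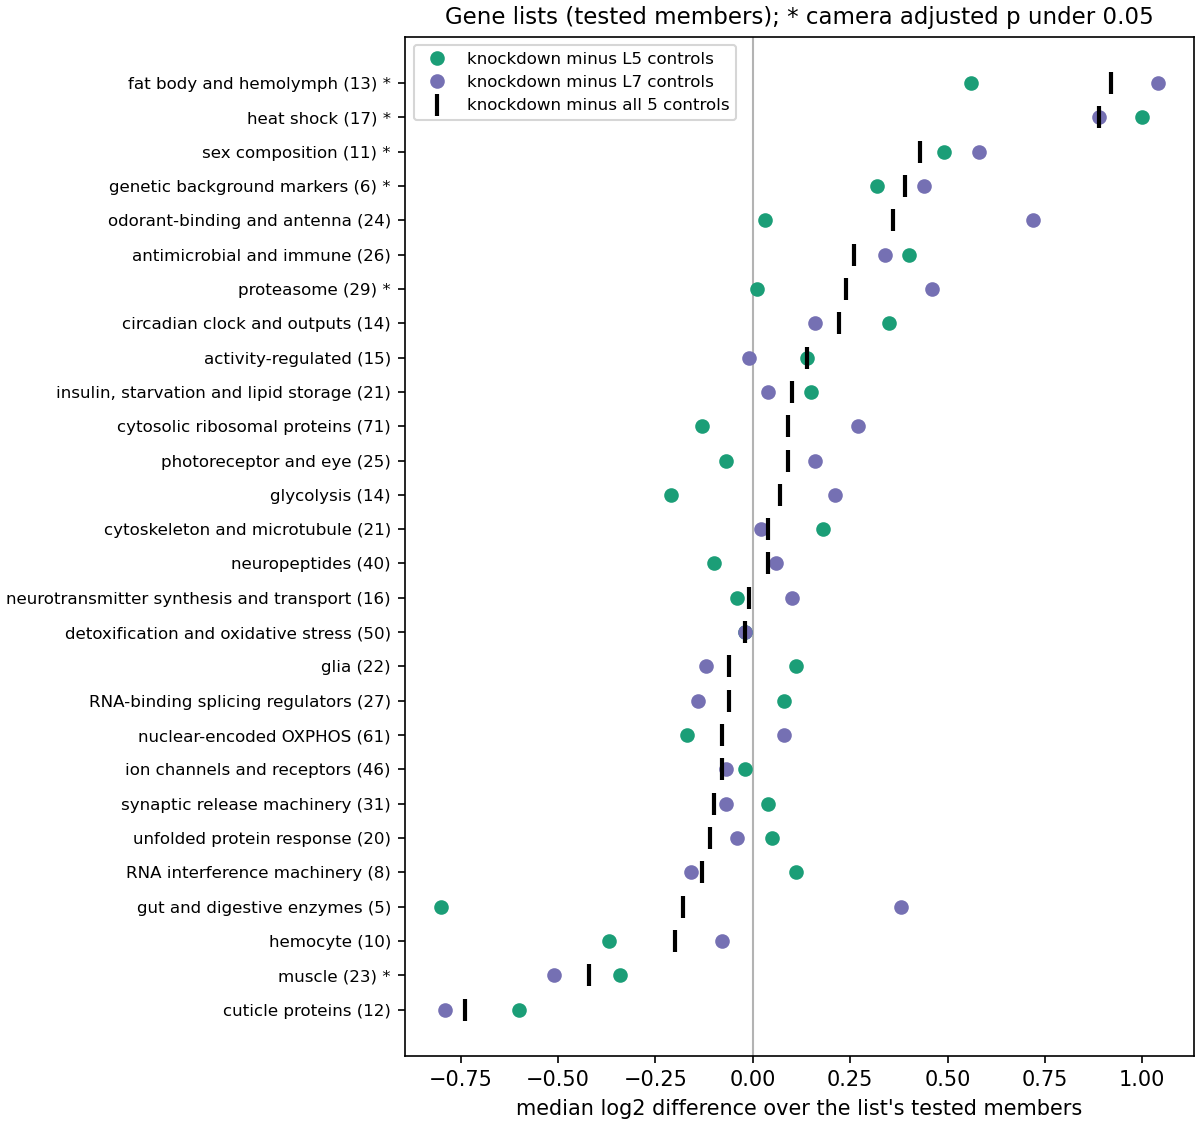
Median log2 difference over the tested members of each of 28 gene lists, for the knockdown libraries (n = 2) against the L5 controls (n = 2), the L7 controls (n = 3) and all 5 controls, where numbers in brackets are tested members. The fat body list stands at 0.56 against L5 and 1.04 against L7 controls, and the proteasome list at 0.01 and 0.46.

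Within neuronal lists single genes changed, and no list passed camera. Of 31 synaptic release genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera, adjusted p = 0.98). The synaptic vesicle SNARE gene nSyb rose from 4844 ± 632 (SD, n = 5) to 11830 ± 897 (SD, n = 2). The kinase gene CaMKII rose 1.66-fold, the NSF gene comt rose 1.49-fold, and the phosphatase gene Synj was 1.52-fold lower. Of 40 neuropeptide genes 1 rose and 2 fell (3 and 2 adjusted over the list alone; camera, adjusted p = 0.936). The insulin-like peptide gene Ilp3 was 1.82-fold lower, Proc (proctolin) was 1.39-fold lower and the glycoprotein hormone gene Gpa2 was 2.24-fold higher. Of 46 ion channels and receptors the serotonin receptor gene 5-HT2A fell 1.66-fold and the potassium channel gene Irk3 rose 1.55-fold (3 rose and 3 fell adjusted over the list alone; camera, adjusted p = 0.936). Of 16 genes for neurotransmitter synthesis and transport 1 fell, the dopamine transporter DAT, by 1.82-fold (1 adjusted over the list alone; camera, adjusted p = 0.936). Of 15 activity-regulated genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera, adjusted p = 0.936). The changed ones were Arc1 and the phosphatase gene puc (1.77-fold), which were lower, and CG30497 (1.69-fold) and the repressor gene h (2.49-fold), which were higher. No gene of the clock list passed among 14 measured, while 4 rose adjusted over the list alone, 6 had an unadjusted limma p under 0.05 and 0 passed by voom (camera, adjusted p = 0.161). The log2 fold changes of its top members were 0.54 for cyc, 0.59 for Lk6, 0.93 for na and 0.53 for tim. Among 27 RNA-binding splicing regulators 1 rose, U2af38 (1 adjusted over the list alone; camera, adjusted p = 0.936). No gene passed limma among 22 glial markers (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 0 by voom; camera, adjusted p = 0.936). Nor did any of 8 genes of the RNA interference machinery (0 adjusted over the list alone, 1 unadjusted, 0 by voom; camera, adjusted p = 0.936). Among 21 cytoskeletal genes 2 rose, the profilin gene chic (1.71-fold) and the spectraplakin gene shot (1.59-fold), with the same 2 adjusted over the list alone (camera, adjusted p = 0.509).

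Metabolic and stress lists also held single changed genes. Of 71 cytosolic ribosomal protein genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera, adjusted p = 0.161). RpS10b stood at 2408 ± 455 (SD, n = 5) against 6261 ± 406 (SD, n = 2), and RpL14 was 2.52-fold, RpL21 1.68-fold and RpLP2 2.76-fold higher. The list's median log2 difference was -0.13 against L5 controls and 0.27 against L7 controls. As a list they were higher against the L7 controls alone (camera, adjusted p = 6.24e-05), with the opposite direction and no call against the L5 controls (0.114). The ribosomal list also passed without control replicate 2 (0.0148), control replicate 3 (0.0435) or knockdown replicate 1 (0.00476), within 6.24e-05 to 0.979 over the alternatives. Of 50 detoxification genes 3 rose and 6 fell (8 and 8 adjusted over the list alone; camera, adjusted p = 0.936). Among them were Cyp6a20 and GstE1 (2.1-fold higher) and the P450 genes Cyp4p2 (3.81-fold lower) and Cyp18a1 (2.13-fold lower), the last a 20-hydroxyecdysone-inactivating enzyme. Cyp4p2 held only 5.2 and 4.9 normalized counts in the knockdown libraries. Of 20 genes of the unfolded protein response the BiP gene Hsc70-3 was 1.93-fold higher and Herp 1.99-fold lower (2 and 1 adjusted over the list alone; camera, adjusted p = 0.98). Of 61 nuclear-encoded respiratory chain genes 2 rose, ND-30 (1.71-fold) and sun (1.48-fold), and 1 fell, ND-51 by 1.52-fold (0 adjusted over the list alone; camera, adjusted p = 0.936). This list was lower against the L5 controls alone (camera, adjusted p = 0.00348), and had the opposite direction and no call against the L7 controls (0.186; 0.00348 to 0.979 over the alternatives). Of 3 measured mitochondrial genome transcripts in the list fixed beforehand none passed limma over all genes (2 at an unadjusted p under 0.05, 0 by voom) and 2 rose adjusted over the list alone. The log2 fold changes were 0.92 for ND4, 1.69 for ND5 and 0.54 for ND1, and this list was too short for camera. Without the filter on low values it had 7 members, 4 of them under a mean of 10, and passed as higher (camera, adjusted p = 0.0091; adjusted p = 0.751 with an estimated correlation). ND1 passed in opposite directions in fits against the controls of 1 lane code, with 1.84 against L5 (limma, adjusted p = 0.00072) and -0.33 against L7 (limma, adjusted p = 0.0321; 0.00072 to 1 over all alternatives). The list pattern did not match the symbols ATP6, CYTB, COX1, COX2 and COX3. Of these COX1 and COX3, given after their values were seen, did not pass, with log2 fold changes of -0.23 ± 0.20 (SE; limma, adjusted p = 0.505) and 0.76 ± 0.49 (SE; limma, adjusted p = 0.373). No gene passed limma among 14 glycolytic genes (0 adjusted over the list alone, 5 at an unadjusted p under 0.05, 0 by voom; camera, adjusted p = 0.936). Of 21 genes of insulin, starvation and lipid storage tobi and the lipase gene bmm (1.85-fold) rose and Ilp3 fell (2 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.936).

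Among markers of other tissues and of immunity, 1 of 26 immune genes rose, the serpin gene nec (1.77-fold), and 1 fell, the NF-kappa-B gene Rel (1.61-fold), with 1 and 1 adjusted over the list alone (camera, adjusted p = 0.161). The immune list was higher without control replicate 1 (adjusted p = 0.028; 0.00959 to 0.806 over the alternatives). Of 10 hemocyte genes the collagen gene vkg fell from 957.4 ± 51.6 (SD, n = 5) to 518 ± 22.9 (SD, n = 2), and 9 did not pass (1 adjusted over the list alone; camera, adjusted p = 0.571). Of 12 cuticle protein genes Cpr47Ea fell 6.83-fold and Cpr47Ef rose 2.53-fold (2 fell and 1 rose adjusted over the list alone; camera, adjusted p = 0.161). Cpr47Ea held only 2.6 and 3.7 normalized counts in the knockdown libraries, so its fold is imprecise. The cuticle list was lower without control replicate 1 (adjusted p = 0.028) or knockdown replicate 2 (0.0331; 0.024 to 0.864 over the alternatives). Of 25 photoreceptor genes 1 fell, the scavenger receptor gene santa-maria, by 1.41-fold (1 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.936). No gene passed limma among 24 odorant-binding and antennal genes (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by voom; camera, adjusted p = 0.161). The antennal list was higher against the L7 controls alone (adjusted p = 0.0381) and without control replicate 2 (0.0362), and had the opposite direction and no call against the L5 controls (0.754; 0.00359 to 0.979 over the alternatives). Of 5 digestive enzyme genes 0 passed (0 adjusted over the list alone, 0 unadjusted, 0 by voom; camera, adjusted p = 0.98). Exons of 22 of the 78 genes named overlap those of another annotated gene. Without a stated counting strand the reads of these, among them fit, U2af38, Hr4, Myo31DF, Fs, ATPCL, l(2)37Bb, tobi, Hsp83, SERCA, Irk3, GstE1, Cpr47Ea, santa-maria, RpS10b and ND-51, may include that gene's.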

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

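The tests of explanations in this part were chosen after the results were seen. The splicing factor gene U2af38 stood at 183.9 normalized counts in control replicate 3, apart from the other controls at 134.5 to 139.2. The antimicrobial peptide gene Drs stood at 1171 in control replicate 1 against 165.6 to 228.5 in the other controls, and Hsp27 at 22.4 in control replicate 4 against 3.3 to 6.4. These 3 lay further from the rest than Dixon's critical value of 0.71, among 94 sets of 5 control values: 78 genes named by the rule, 15 further genes chosen after their values were seen, and the read totals. Chance gives about 1 in 20, or 4.7 of 94, a share that does not hold for genes picked by their values, such as Drs and Hsp27.

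The 445 genes that differ between knockdown and control brains were reached by 1 of the 21 splits of the libraries into 2 and 5, the real one, and the highest other, the L5 control pair, gave 139. Libraries group by lane code, 19 splits break a lane code and gave 0, and the 2 that keep lane codes whole are too few for a share under 0.05. Lower depth of the knockdown libraries as the whole cause is argued against by thinning all libraries to 3260649 reads, which left 375 genes, 364 of them among the 445. A batch effect of date or lane cannot be told apart from the knockdown, since the knockdown libraries have a date and lane code of their own and control libraries of lane codes L5 and L7 already differed in 2057 genes. The effect of losing circMbl stays open for the same reason.

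Yp3, fit and tobi, yolk protein and fat body transcripts, rose in the knockdown libraries. More fat body left on the brains is a candidate explanation: over the 13 list members the knockdown's log2 changes correlated with those between control libraries of title numbers 3 and 2 at equal lane code (Pearson r = 0.59, permutation p = 0.0421; Spearman rho = 0.55, permutation p = 0.0527; r = 0.9 without Obp99b and Lsp2, the farthest from the median), the 1 relation tested, across genes, which are not independent replicates. Obp99b, higher by 1.94 between those controls, had a knockdown log2 fold change of 0.22. It went against the relation, so the r of 0.9 without it adds no support. A higher share of females in the knockdown samples would give the same correlation for yolk protein genes and cannot be told apart by the male-specific RNAs, with a log2 fold change of 0.08 for roX2 and -0.64 for roX1, since a small share of females in the controls could multiply with little loss of male RNA. An effect of the knockdown itself was not tested apart from these.

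Transcripts of the mitochondrial genome moved unequally: ATP6 rose 13.2-fold and CYTB 2.79-fold, and COX2, described after its values were seen, stood at 0, 0.9, 2.7, 0 and 1.6 normalized counts in the controls against 68.9 and 58.5. An equal rise of all mitochondrial RNA as the whole cause is argued against by log2 fold changes of -0.23 ± 0.20 (SE) for COX1 and 0.76 ± 0.49 for COX3 (1.68 against the L5 controls) beside 3.73 ± 0.18 for ATP6. A smaller general rise stays open, since 7 of 8 measured transcripts lay above 0, and 6 of 8 against the L7 controls, where ND1 (-0.33) was also below 0. A batch effect on single transcripts cannot be told apart from the knockdown: COX3 differed by a log2 of -1.55 and ND1 by -2.17 between the L5 and L7 controls, while ATP6 differed by -0.15. A sequence difference between mitochondrial genomes of the strains was not tested.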

How the results depend on the processing

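The test against each lane code, the thinned reads and the estimated correlation without a filter were chosen after the data were seen, and the other alternatives were planned. The count of 445 genes stayed within 1.5 times with another pseudocount, filter, scaling, robust variance, voom on the recovered reads (344), thinned reads (375) and the test against each lane code (452). Quantile normalization gave 490. Rises made up 56.9% of the calls, 69.1% without a filter (345 of 499) and 70.6% with voom (243, with 101 falls), but 49.3% with library weights, 48.9% with averaged controls and 44.4% against the L7 controls. Other settings moved the count: 261 without a variance trend, 1777 with library weights, 1301 with same-titled controls averaged, 741 with title number as a random effect (fitted correlation -0.504 across lane codes, no test of shared RNA), 2409 against the L7 and 1082 against the L5 controls in fits without the others, 65 at an adjusted p under 0.01 and 145 with at least 2-fold change. The cause was not tested except where the threshold itself is stricter. Leaving out 1 library gave 1 to 663 genes (202, 177 and 133 without control replicates 1, 4 and 5, 1 without knockdown replicate 1 and 1 without knockdown replicate 2) and 5 to 8 lists. As a replicate block, the source name number gave 120 genes and 5 lists and the title number 51 genes and 8 lists. A number held by 1 library takes that library out of the comparison. These were control replicates 3, 4 and 5 for the source name number and control replicate 1 for the title number. The block counts thus rest on fewer libraries than the 445. Neither number has a stated origin. Deviations of control and knockdown libraries correlated across genes at 0.18 and 0.23 in the 2 pairs of equal source name number, too few to show pairing, and at -0.04 to 0.23 in those of equal title number. The count of 6 lists fell to 0 with an estimated correlation (camera; 1 at an unadjusted p under 0.05) and was 4 to 8 elsewhere. The heat shock and muscle lists were lost without knockdown replicate 1, and that of background markers without control replicate 3 or 5 or knockdown replicate 2. With the source name number as a block the muscle (0.29) and background marker (0.142) lists were lost and the antennal list (0.00359) was gained; with the title number the cuticle (0.024) and immune (0.00959) lists were gained. The ribosomal list passed with library weights (0.00608) and averaged controls (0.0446). Directions turned, without a call, for the antennal (adjusted p = 0.754) and ribosomal (0.114) lists against the L5 controls and for the respiratory chain list with quantile normalization (0.977), library weights (0.717), averaged controls (0.934) and L7 controls (0.186); leaving out 1 library gave 0.299 to 0.938 for that list, with the turned direction without control replicate 2 or 3 or knockdown replicate 1. The log2 fold change of mbl stayed between -0.62 and -0.36 and passed in 6 of 24 alternatives: -0.445 with library weights, -0.48 with same-titled controls averaged, -0.50 with the random effect, -0.41 against the L7 controls, -0.61 against the L5 controls and -0.41 against each lane code. Its adjusted p-values ran from 0.00946 to 0.37 over all alternatives. None of the 62 named genes that passed reversed in any of 1482 values, of which 363 no longer passed. Of genes that had not passed, roX2 turned to -0.052 with library weights, -0.001 with averaged controls and -0.13 against the L7 controls and each lane code, and lay between -0.032 and 0.187 without single libraries (below 0 without control replicate 2 or knockdown replicate 2). ND1 turned to -0.033 with library weights and -0.33 against the L7 controls and each lane code; it passed downward against L7 and upward against L5 (1.84). The rescaling, with 1 factor for all libraries, left 7278 genes tested and 445 called, and tests no difference in scaling. The edgeR and DESeq2 tests planned on recovered reads were not run. The deposited table as a whole, with its misplaced stretch, does not pass as recoverable reads, although its intact lines do, and voom was run on those. List tests were not run with the random effect, voom or each lane code. Depth limits genes near 10 normalized counts. Of simulated 1.5-fold changes 28.4% were found, and the part of depth in that was not tested.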

Other observations

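Genes in this part lie outside the naming rule and were chosen after their values were seen. The non-coding RNA CR40469, near the tip of X (122493 to 122706), rose from 12320 ± 2480 normalized counts (SD, n = 5) to 50330 ± 904 (SD, n = 2; limma, adjusted p = 0.00457). The histone H3.3 gene His3.3B rose from 23420 ± 2860 to 55170 ± 226 (limma, adjusted p = 0.00673). The transporter gene Mdr50, which lay between 1.1 and 3.6 in the controls, stood at 101.4 and 51.2 in the knockdown libraries (limma, adjusted p = 0.00479). The largest fall among genes with a bare CG number was that of CG7214, from 854.9 ± 446 (SD, n = 5) to 69 ± 9.28 (SD, n = 2). On 3R, CG10553 (25316461 to 25318111) was 2.99-fold lower, close to the named gene CHKov2 (25329530 to 25331203). The named gene tobi (25344761 to 25346921), which rose 5.9-fold, also lies near CHKov2. Whether these changes are linked was not tested.

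Changed genes were spread over the chromosome arms, from 5% of tested genes on 2L to 7.3% on X. Within 250 kb of y 1 of 24 other tested genes had changed, and within 250 kb of w 3 of 32. Inducible heat shock genes stood apart in knockdown replicate 1: Hsp26 held 4953 normalized counts there, against 630.9 in knockdown replicate 2 and 156.4 to 862.6 in the controls, and Hsp22 held 1275 against 153.5 and 29.6 to 219.5. The rhodopsin gene ninaE held 1840 and 2072 in the controls with title number 3, 445.2 and 459.3 in those numbered 2, 584.9 in the control numbered 1, and 599.2 and 1920 in the knockdown libraries numbered 2 and 3.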
